A study of Homo sapiens with 9 samples.

How the data were processed

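RNA sequencing was done on 9 human dorsal root ganglion (DRG) cultures in 3 groups of 3 donors. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and libraries were made with the NEBNext Ultra II RNA kit. The submitters' processing notes name edgeR, without a version or a role, and the genome build GRCh38. The aligner, the counting tool, the gene annotation and any filter on genes are not given in the sources used here.

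The deposited table holds log2 expression values for 20369 Ensembl genes in the 9 libraries. No value lies below -3.56, a minimum shared by all libraries, and the highest is 13.2. After this minimum (0.0846 on the linear scale) was subtracted, between 72.9% and 74.5% of the values above 0 in each library were whole multiples of a common step, at a tolerance of 0.001. A deposited value is therefore read here as the log2 of an estimated count scaled to library size (CPM) plus a constant of 0.0846, with library totals scaled per library. The step gave totals of 19.9 M to 29.6 M estimated counts per library. A count of 0 in a library allows up to 3 counts, or 0.102 to 0.149 CPM across the libraries. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Whole counts were recovered for only that part of the values, so tests made for whole counts, which had been planned for that case, were not run.

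Gene symbols were matched by Ensembl identifier for 20366 of the 20369 genes. Coordinates are those of GENCODE 29 on GRCh38, in which 19455 of the identifiers were found. The counting by strand is not given, and genes with near-identical copies, such as the HLA genes, are uncertain where reads can be shared.

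The 3 comparisons were cytokines plus isotype against PBS, cytokines plus dupilumab against cytokines plus isotype, and cytokines plus dupilumab against PBS. All 9 libraries entered a single limma fit (limma 3.58.1 in R 4.3.3) on the deposited log2 values, with a mean-variance trend and no donor term. Genes with at least 1 CPM (a log2 value of 0 or more) in at least 3 libraries were tested, which left 16942. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Libraries with the same replicate number come from the same donor, per the labels. Their deviations from the group means were compared across the 9 same-donor pairs and correlated at 0.59 to 0.77, against -0.55 to -0.04 for libraries of different donors. The latter values are no independent comparison, since deviations add to 0 within each group and so pull them below 0. The first principal component held 45.9% of the variance and the second 22.8%. The share of their variance that lay between donors was 0.98 for both, and the share of the third, with 10.7%, that lay between groups was 0.95. The fit with donor as a block is therefore printed beside the counts and genes it alters, and for lists where stated. Both fits give the same log2 changes, since every donor is in every group, and differ in their standard errors. Without the block the differences between donors add to the standard errors.

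Before the data were examined, 28 gene lists were fixed, covering cytokine signalling and response, itch and pain receptors, neuronal, glial, stromal, vascular and immune cell markers, and stress and metabolism. The 27 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The list of red blood cell transcripts had too few tested members. In cytokines plus isotype against PBS, camera called 9 lists, of which 3 kept their call with an estimated correlation. In cytokines plus dupilumab against cytokines plus isotype it called 6 lists, of which 2 kept it, and in cytokines plus dupilumab against PBS it called 17 lists, of which 3 kept it. With donor as a block these numbers were 14 and 2, 10 and 2, and 21 and 0.

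Genes were named by a rule fixed in advance. It took, per comparison and direction, up to 10 genes past the threshold with the same sign in all 3 donors and the smallest p, filled from the fit with donor as a block where the fit without it gave fewer. It also took up to 4 members per list with the smallest p without the block or, where a member passed only there, with it, 20 genes of cytokine signalling, itch and sensory neurons (1 of them not reported here), and the 5 leading genes of cytokines plus dupilumab against PBS. Genes without an approved-style symbol were counted and not named, and 13 genes that differ with a donor's sex were left out of all tables.

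The procedure was tested on simulated data for cytokines plus isotype against PBS, with the donor effects and spreads of the 16942 tested genes and 200 changed genes in each of 10 draws. Without the block, 0% of genes changed by 0.5 (log2), 23.8% of those changed by 1 and 65.1% of those changed by 2 were recovered. With donor as a block these shares were 41.0%, 71.9% and 91.4%, and 4.08% of the calls were false. The simulated residuals were independent between genes, and a changed gene had the same effect in every donor. The share of false calls in the measured data can therefore differ from 4.08%. Correlations between comparisons that share libraries are printed beside values from 100 simulations of unchanged groups. In 20 simulations for overlaps the unchanged groups gave 0 calls in cytokines plus isotype against PBS, so overlaps are printed beside those of independent lists.

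The alternatives tried were the donor block as a fixed and as a random effect, other pseudocounts (0.1 and 5), no filter and a filter at 5 CPM, median-ratio scaling, quantile normalization, only the 6 libraries compared, array weights, no mean-variance trend, and leaving out each donor and each library. The fit with voom on the recovered estimated counts, and the blocked fits without each library, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.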

Results

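RNA from cultures of human dorsal root ganglia, which hold the cell bodies of sensory neurons together with glial, stromal and immune neighbours, was sequenced in 3 groups of 3 libraries. The control cultures received PBS. The other groups received interleukin 4 and interleukin 13, the type 2 cytokines of allergic inflammation, either with an IgG4 isotype control antibody or with dupilumab, an antibody that blocks the interleukin 4 receptor alpha chain shared by both cytokines. Each of the 3 donors contributed a library to every group. Expression is given as deposited log2 values of estimated counts scaled to library size (log2 CPM), from 19.9 M to 29.6 M estimated counts per library. The study concerns type 2 cytokines, sensory nerves and itch, so the comparisons ask how the cultures responded to the cytokines and how much of that response dupilumab took away.

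Cytokines plus isotype were compared with PBS to ask what the cytokines changed. Cytokines with isotype raised well-known interleukin 4 and 13 target genes by large factors and lowered neutrophil-attracting chemokines. PBS held no antibody, so an effect of the isotype antibody cannot be told apart from that of the cytokines. CCL26, which encodes the eosinophil attractant eotaxin 3, went from -0.77 ± 1.09 (SD, n = 3) in PBS to 5.91 ± 0.59 with cytokines, a 103-fold rise. ALOX15, a lipoxygenase of alternatively activated macrophages, rose from -1.17 ± 1.43 to 5.94 ± 0.78. Both rises start from few counts, so their sizes are uncertain. In PBS ALOX15 was at -2.42 in replicate 3, the floor of 3 counts in that library. CCL26 was at 0.49, -1.49 and -1.31 in PBS replicates 2, 3 and 4. The neutrophil attractant CXCL5 fell by 3.14 on the log2 scale, from 9.29 ± 0.29 to 6.15 ± 0.53. In all, 27 of 16942 genes passed the threshold without a donor term (limma, 21 higher and 6 lower), each changed at least 2-fold and with the same sign in 3 of 3 donors. A fit with donor as a block passed 711 genes, 487 higher and 224 lower, all 27 among them. Of the 711, 175 rose and 58 fell at least 2-fold. Without the block the count was 1 without the libraries of replicate 2 and 0 without those of replicate 3. With it the count was 308 and 334 without these, ranged from 299 to 811 without single donors or libraries, and was 407 with donor as a random effect.

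Among 33 tested members of the list of textbook interleukin 4 and 13 response genes, 7 rose and 0 fell without the block, or 20 and 1 adjusted over the list alone. With the block 23 rose and 1 fell, or 25 and 3 adjusted over the list alone. The list's median change was 1.54 (log2; camera adjusted p = 2.94e-43, and adjusted p = 9.59e-04 with an estimated correlation). The lectin CLEC10A rose by 3.39 ± 0.29 (SE; adjusted p = 0.0027) and the interleukin 1 antagonist IL1RN by 4.94 ± 0.44 (adjusted p = 0.0037). CISH and SOCS1 encode feedback inhibitors of JAK-STAT signalling. CISH rose by 2.66 ± 0.31 (adjusted p = 0.0165), and SOCS1 rose with the block only, by 2.68 ± 0.34 (adjusted p = 0.0807 without the block and 8.49e-04 with it). FCER2, the low-affinity IgE receptor, was listed at 0 in 2 of the 3 PBS libraries and had a mean of 2.71 ± 1.49 with cytokines (adjusted p = 0.0233). The chemokine CCL18, the transglutaminase F13A1 and the lectin CD209 rose with the block only, by 5.78 ± 0.29, 5.41 ± 0.21 and 4.06 ± 0.20, with adjusted p of at most 6.51e-07. CCL18 was at -0.57 ± 1.64 (SD) in PBS, so the sizes of its changes against PBS also start from few counts and are uncertain. With the block CCL2, a monocyte attractant, fell by 0.82 (adjusted p = 5.97e-04).

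The 10 higher genes with the smallest p without the block were led by RNASE1, a secreted ribonuclease gene on chromosome 14 (20801228 to 20803278, GRCh38), which went from 3.84 ± 0.18 to 6.42 ± 0.16 (adjusted p = 6.16e-04). CCL26 lies on chromosome 7 (75769533 to 75789896) and rose by 6.68 ± 0.52 (adjusted p = 0.0021). ALOX15 lies on chromosome 17 (4630902 to 4642294) and rose by 7.11 ± 0.69 (adjusted p = 0.0051). CLEC10A, IL1RN and CISH were also among the 10. The others were CD180, a toll-like receptor homologue (3.45 ± 0.27), SEMA4A, a semaphorin (2.99 ± 0.28), IL1RL1, the receptor for interleukin 33 (4.28 ± 0.47), and SIGLEC8, a sialic acid receptor of eosinophils and mast cells (3.29 ± 0.38), with adjusted p of at most 0.0165.

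Chemokines and myeloid genes were among those that fell. Without the block MARCO, a macrophage scavenger receptor, fell by 3.67, CLEC5A, a myeloid lectin, fell by 4.88, and CYBB, the catalytic subunit of the phagocyte NADPH oxidase, fell by 3.53. The chemokine CXCL2 fell by 2.42 and CXCL3 fell by 2.69, and the adjusted p of these 5 genes was at most 0.0233. From the fit with the block, the cytokine IL1B fell by 1.68, the chemokine CCL20 fell by 4.35, CXCL8 fell by 2.61 and VSIG4, a complement receptor of resident macrophages, fell by 2.51, with adjusted p of at most 3.50e-06. CLEC5A and CCL20 fell to few counts (-0.77 ± 0.71 and -0.40 ± 1.65, SD, with cytokines), so the sizes of their falls are uncertain. Of 23 members of the list of NF-kB response genes, 2 fell and 0 rose without the block (9 and 0 adjusted over the list alone). With the block 16 fell and 1 rose (20 and 1 adjusted over the list alone). The list's median was -0.78 (camera adjusted p = 1.16e-24, and adjusted p = 0.0011 with an estimated correlation). The member that rose, VCAM1, an endothelial adhesion molecule, was named after its values were seen (0.79 ± 0.10, adjusted p = 0.0010 with the block).

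Of 40 chemokines and inflammatory cytokines, 2 rose and 3 fell without the block (5 and 9 adjusted over the list alone), and 5 rose and 15 fell with it (6 and 18 adjusted over the list alone). The higher genes without the block were CCL26 and CCL24 (4.18 ± 0.50), which encode eosinophil attractants. This list's median was -0.36 (camera adjusted p = 2.39e-05, adjusted p = 0.0148 with an estimated correlation, and adjusted p = 0.0963 with the block and an estimated correlation).

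Markers of myeloid cells moved in both directions. Of 25 macrophage and myeloid markers, 0 rose and 1 fell without the block (3 and 3 adjusted over the list alone), and 8 rose and 4 fell with it (11 and 4 adjusted over the list alone). With the block the integrin ITGAM rose by 1.54 ± 0.12 (adjusted p = 2.74e-05) and MS4A6A by 2.50 ± 0.28 (adjusted p = 3.43e-04), whereas CD14, the lipopolysaccharide co-receptor, fell by 2.01 (adjusted p = 1.48e-05) along with MARCO and VSIG4. The median of this list was 0.36 (camera adjusted p = 0.0246, adjusted p = 0.626 with an estimated correlation). Of 19 genes of MHC class II presentation 0 rose without the block (3 adjusted over the list alone) and 11 rose with it (12 adjusted over the list alone), and 0 fell in either fit. With the block HLA-DPB1 rose by 1.01 ± 0.10 (adjusted p = 1.34e-04) and CD74, the class II chaperone, by 0.60 ± 0.10 (adjusted p = 0.0045). The class II list had a median of 0.52 (camera adjusted p = 5.49e-08, adjusted p = 0.107 with an estimated correlation). With the block camera gave adjusted p = 2.4e-09, and 0.300 with an estimated correlation. HLA genes have near-identical relatives, and how reads were shared between them is not given.

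Stromal genes passed the threshold with the block only. Of 26 fibroblast markers 8 rose and 0 fell with it (10 and 2 adjusted over the list alone), against 0 and 0 without it (4 and 0 adjusted over the list alone). POSTN, a matrix protein induced by interleukin 13, rose by 2.74 ± 0.30 (adjusted p = 2.96e-04), PDGFRA by 1.32 ± 0.10 (adjusted p = 2.74e-05) and COL6A1 by 1.15 ± 0.10 (adjusted p = 6.24e-05). The fibroblast list's median was 0.20 (camera adjusted p = 1.93e-07, adjusted p = 0.442 with an estimated correlation). With the block camera gave adjusted p = 3.22e-06, and 0.300 with an estimated correlation. Of 50 extracellular matrix genes 6 rose and 6 fell with the block, and the list was not called (camera adjusted p = 0.277). The proteoglycan VCAN fell by 1.88 (adjusted p = 0.0014) and CCN2, a matricellular growth factor, fell by 1.04 (adjusted p = 0.0015). Of 16 endothelial markers PLVAP and CLDN5 rose and CDH5 and ROBO4 fell with the block.

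Sensory neuron genes changed little in size, and more of them fell than rose. None of 38 pan-neuronal and sensory neuron markers passed without the block, over all genes or adjusted over the list alone, and with it 5 fell and 0 rose (15 and 2 adjusted over the list alone). The neurofilament genes NEFM (-0.42), NEFH (-0.40) and NEFL (-0.33), the glutamate transporter gene SLC17A6 (-0.30) and the synaptic gene SNAP25 (-0.32) fell. Their adjusted p with the block were at most 0.0469. The neuronal list's median was -0.17 (camera adjusted p = 0.0420, adjusted p = 0.743 with an estimated correlation). With the block camera gave adjusted p = 3.96e-07, and 0.300 with an estimated correlation. Of 38 synaptic genes 5 fell and 1, the glutamate receptor gene GRIA1, rose with the block (16 and 1 adjusted over the list alone). The synaptic list had a median of -0.21 (camera adjusted p = 0.0060, adjusted p = 0.743 with an estimated correlation). With the block camera gave adjusted p = 3.52e-09, and 0.273 with an estimated correlation, while fry called the synaptic list lower (adjusted p = 0.0353). Of 40 nociceptor channels and receptors 1 passed, the potassium channel gene KCNQ3, which fell by 0.47 with the block (adjusted p = 0.0440). The nociceptor list had a camera adjusted p = 0.141 without the block. With the block fry called it lower too (adjusted p = 0.0316, against 0.920 without the block). Among 25 sensory neuropeptide and processing genes, RAMP1, a subunit of the receptor for the peptide CGRP, rose by 3.01 ± 0.41 without the block (adjusted p = 0.0287). CALCRL, the other subunit, rose by 0.58 ± 0.10 with the block (adjusted p = 0.0085), and the peptide gene ADCYAP1 fell by 0.37 (adjusted p = 0.0345). Adjusted over the list alone, 8 of these 25 genes fell and 2 rose with the block.

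Some itch receptors passed the threshold. Of 35 itch receptors and pruriceptor peptides, IL1RL1 rose without the block, and with it 3 rose and 2 fell (5 and 2 adjusted over the list alone). Over all 16942 genes 711 passed with the block. HRH2, a histamine receptor, rose by 1.11 ± 0.20 (adjusted p = 0.0105), HTR2B, a serotonin receptor, fell by 1.80 (adjusted p = 0.0097) and the sphingosine phosphate receptor S1PR1 fell by 0.70 (adjusted p = 0.0015). The itch list was not called, with a median of -0.07 and a mean of 0.06 (camera adjusted p = 0.954). The itch cytokine receptor genes IL31RA (-0.15, 95% interval with the block -0.32 to 0.03) and OSMR (-0.03, adjusted p = 0.865 with the block) did not pass in either fit. Nor did the capsaicin receptor gene TRPV1 (-0.24, interval -0.38 to -0.09, adjusted p = 0.0775 with the block), TRPA1 (-0.02), the sodium channel gene SCN9A (-0.23), the peptide genes CALCA (-0.18), TAC1 (-0.25) and NPPB (-0.59), or the axon growth and injury genes GAP43 (0.04) and ATF3 (0.05). The intervals of SCN9A (-0.38 to -0.07), CALCA (-0.325 to -0.0445) and TAC1 (-0.43 to -0.07) with the block also lay below 0. These genes and TRPV1 were lower in 3 of 3 donors, and the intervals are not adjusted for the number of genes. The interval of STAT6 with the block (0.005 to 0.24) lay above 0. None of 17 receptor and JAK-STAT components passed in either fit, IL4R (-0.12), IL13RA1 (0.03), IL13RA2 (0.10), IL2RG (0.25), STAT6 (0.12) and JAK1 (-0.13) included. Receptor expression in PBS was 5.34 ± 0.34 for IL4R and 6.80 ± 0.11 for IL13RA1.

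Of 46 axon guidance and neurotrophic factor genes 5 rose and 2 fell with the block, with SEMA5A higher by 1.32 ± 0.14 and SEMA4A the member past the threshold without it, and the list was not called (camera adjusted p = 0.0926). Of 23 complement and coagulation genes 3 rose and 5 fell with the block, and this list, whose median was -0.04 and mean 0.24, was not called either (adjusted p = 0.882). The list of mitochondrially encoded transcripts was called lower, although 0 of its 13 members passed in either fit, with a median of -0.13 (camera adjusted p = 0.0420, adjusted p = 0.651 with an estimated correlation). With the block the lists of nociceptor genes (adjusted p = 0.0091), sensory neuropeptides (0.0011), axon growth and nerve injury (0.0253), hypoxia and glycolysis (0.0063) and cholesterol synthesis (0.0227) were called lower as well, with adjusted p of 0.181 to 0.548 with an estimated correlation. In the hypoxia list VEGFA fell by 0.53 (adjusted p = 0.0044). Lists of receptor components, satellite glia, Schwann cells, mural cells, endothelium, lymphocytes and mast cells, interferon response, cell cycle and immediate early genes were not called by camera in either fit. With the block fry called the satellite glia list higher (adjusted p = 0.0461, against 0.842 without the block). The endothelial list's median was -0.06 and its mean 0.00.

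**Figure D1:**
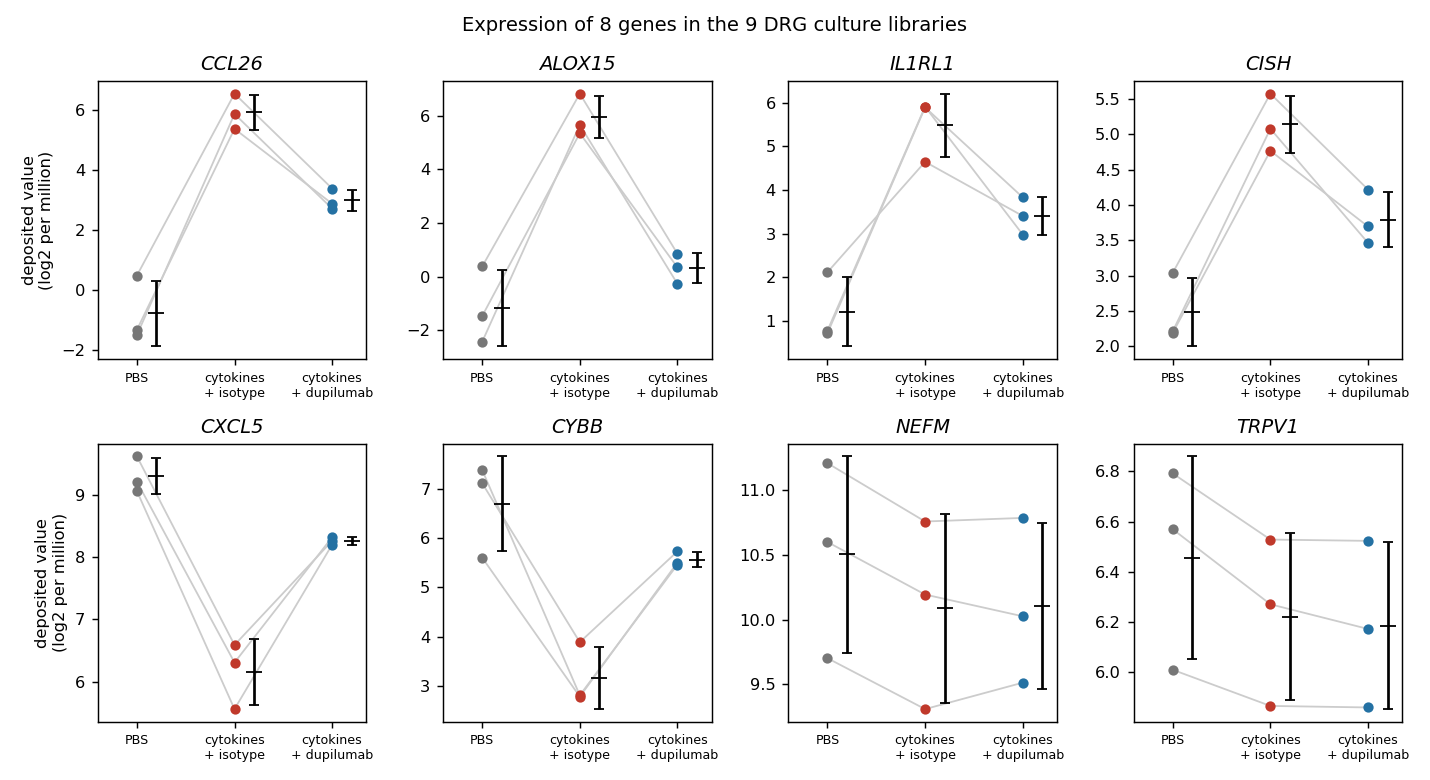
Deposited log2 expression of 8 genes, with a point per library, grey lines joining the libraries of a donor, and bars for mean ± SD (n = 3); each panel has its own vertical range. CCL26 and CXCL5 move in opposite directions with cytokines and part of the way back with dupilumab, while NEFM and TRPV1 differ more between donors than between groups.

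Cytokines plus dupilumab were compared with cytokines plus isotype to ask what the antibody to the receptor changed. Cytokine-induced genes were lower and cytokine-repressed chemokines higher with dupilumab, but most of these differences passed the threshold only with donor in the fit (0 to 8 genes without it). ALOX15 fell by 5.62 (adjusted p = 4.50e-05), to 0.32 ± 0.56 (SD, n = 3), and CXCL5 rose by 2.11 ± 0.14 (adjusted p = 5.21e-05). Without the block 0 genes passed (limma, 157 at an unadjusted p under 0.05, smallest adjusted p 0.106), and voom without the block also gave 0. Those 157 are below a share of 0.05 of the 16942 tested genes, which unchanged genes would give on average. Donor differences enter the spread of the fit without the block, so its 0 is weak evidence of no effect. With the block 100 genes passed, 29 higher and 71 lower, each with the same sign in 3 of 3 donors. The count with the block was 55 without replicate 2 and 36 without replicate 3, ranged from 36 to 175 without single donors or libraries, and was 68 with donor as a random effect.

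Among the lower genes of the blocked fit, F13A1 fell by 3.09, CCL18 fell by 3.01, CCL26 fell by 2.92 and CD209 fell by 2.37. The cysteine protease gene CTSC fell by 1.68, the dendritic cell marker CD83 fell by 1.55, CISH fell by 1.35, the protease inhibitor SPINT2 fell by 1.15 and the membrane peptidase MME fell by 1.06. The adjusted p of these 9 genes was at most 5.74e-04. The higher genes included CLEC5A (3.37 ± 0.27, SE with the block), CCL20 (2.66 ± 0.20), CYBB (2.40 ± 0.29), MARCO (2.30 ± 0.24), VSIG4 (2.20 ± 0.15), CXCL3 (1.78 ± 0.12), CD14 (1.42 ± 0.14), CXCL8 (1.24 ± 0.14) and IL1B (0.67 ± 0.07), with adjusted p of at most 0.0026. The rises of CLEC5A and CCL20 start from few counts, so their sizes are uncertain. SOCS1 fell by 1.76 (adjusted p = 0.0475) and RAMP1 fell by 2.25 (adjusted p = 0.0191).

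Of 33 textbook response genes 18 fell and 0 rose with the block (23 and 0 adjusted over the list alone), and 0 fell without it (15 adjusted over the list alone). The median of the response list was -0.98 (camera adjusted p = 1.00e-44, and adjusted p = 8.70e-04 with an estimated correlation). Of 23 NF-kB response genes 6 rose and 1, VCAM1, fell with the block. The median of the NF-kB list was 0.29 (camera adjusted p = 1.35e-11, and adjusted p = 0.0089 with an estimated correlation). The lists of cell cycle genes (median 0.17, camera adjusted p = 1.82e-08) and of lymphocyte and mast cell markers (median 0.19, adjusted p = 0.0037) were called higher. Those of MHC class II genes (median -0.16, adjusted p = 0.0016) and interferon response genes (median -0.06, adjusted p = 0.0418) were called lower. With the block 1 MHC class II gene fell, and 0 members of the other 3 lists passed in either fit. With an estimated correlation these 4 lists had adjusted p = 0.367, 0.568, 0.367 and 0.572. With the block the lists of chemokines (adjusted p = 0.0012), extracellular matrix (9.78e-04) and endothelial markers (0.0018) were also higher and that of synaptic genes (0.0181) lower, and none kept its call with an estimated correlation (adjusted p of 0.177 or more).

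No member of the pan-neuronal, nociceptor or itch lists passed over all genes in this comparison in either fit. Adjusted over the list alone with the block, 1 itch gene rose and 1 fell, against 0 in the pan-neuronal and nociceptor lists. IL1RL1, which the cytokines had raised, was at 5.90, 5.91 and 4.65 with isotype in replicates 2, 3 and 4. With dupilumab it was at 3.83, 2.98 and 3.41. The pan-neuronal list's median was -0.03 (camera adjusted p = 0.612), with NEFM at 0.02 and NEFL at -0.01. IL31RA (-0.07, 95% interval with the block -0.24 to 0.11), TRPV1 (-0.04, interval -0.18 to 0.11), CALCA (-0.03), SCN9A (0.04), IL4R (0.12) and STAT6 (0.01) did not pass. Nor did IL13RA1 (0.17), whose interval with the block (0.02 to 0.32, not adjusted for the number of genes) lay above 0.

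Among the genes changed with cytokines plus isotype against PBS, most had a change of the opposite sign with dupilumab. All 27 genes past the threshold without the block had the opposite sign with dupilumab against isotype, as had 645 (90.7%) of the 711 past it with the block. These genes were chosen on isotype libraries that both comparisons share, which favours opposite signs. No simulated share was computed for genes chosen this way. Over all 16942 genes 63.0% had opposite signs, fewer than the 66.7% in simulated unchanged groups that share those libraries. The median share of the cytokine change that remained was 45.1% over the 27 genes (49.8% for the 21 higher and 33.5% for the 6 lower). Over the 711 it was 57.3%, with quartiles across genes of 41.2% and 77.7%. In single donors the median over the 711 was 58.4%, 45.2% and 71.8% (replicates 2, 3 and 4). Of the 100 genes that dupilumab changed with the block, 97 were among the 711 and moved the opposite way. Of these, 68 rose with the cytokines and fell with dupilumab, where independent lists of those lengths would share 2.04, and 29 did the reverse, where 0.383 would be shared. Part of that excess may come from the shared isotype libraries, which are too few to be divided between the comparisons, and simulated unchanged groups gave 0 calls for cytokines plus isotype against PBS and so no overlap to compare. Across the 16942 genes, which are not independent replicates, the changes of these comparisons correlated at -0.65 (covariance -0.0673). Simulated unchanged groups that share the isotype libraries gave -0.50 (covariance -0.0279, a difference of -0.0394).

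**Figure D2:**
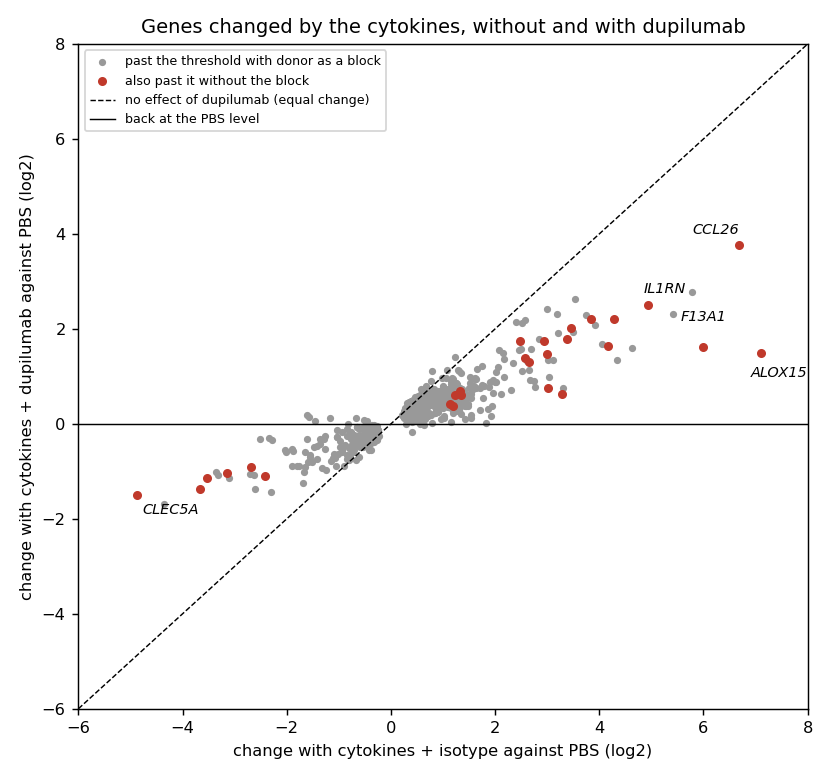
Change against PBS (log2) with cytokines plus isotype (horizontal axis) and with cytokines plus dupilumab (vertical axis), a point per gene, for the 711 genes past the threshold with donor as a block (grey) and the 27 also past it without the block (red). Points on the dashed line kept their whole change and points on the solid horizontal line were back at the PBS level; the median share remaining was 57.3% over the 711 genes.

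Cytokines plus dupilumab were compared with PBS to ask what remained of the cytokine response. A smaller change in the same direction remained, and nearly all of it passed the threshold only with donor in the fit (0 to 1 genes without it). Both cytokine groups held an antibody and PBS none, so an effect of the antibodies cannot be told apart from a remaining cytokine response. CCL26 was still 3.76 ± 0.25 (SE) higher than in PBS (adjusted p = 1.95e-04), and IL1B fell by 1.01 (adjusted p = 1.95e-04). Without the block 0 genes passed (limma, 188 at an unadjusted p under 0.05, smallest adjusted p 0.115), and voom without the block gave 0. Those 188 are again below a share of 0.05 of the 16942 tested genes, so this 0 is weak evidence of no difference. With the block 193 genes passed, 142 higher and 51 lower, and the count was 24 without replicate 2 and 69 without replicate 4. It ranged from 24 to 390 without single donors or libraries and was 28 with donor as a random effect. Of the 193, 164 had also changed with cytokines plus isotype, 123 higher and 41 lower in both. Independent lists would share 4.08 and 0.674, and part of the excess may come from the shared PBS libraries. Across genes the changes of the comparisons against PBS correlated at 0.70 (covariance 0.0762), against 0.50 (covariance 0.0279) in simulated unchanged groups that share them (a difference in covariance of 0.0482), and 76.8% of all genes had the same sign against 66.7%.

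The 5 genes with the smallest p with the block were CCL26, IL1B, ANPEP, RNASE1 and SCUBE3. ANPEP, a membrane aminopeptidase, rose by 1.75 ± 0.13, RNASE1 by 1.39 ± 0.12 and SCUBE3 by 2.32 ± 0.20, with adjusted p of at most 6.21e-04. CCL18 (2.77 ± 0.29), F13A1 (2.32 ± 0.21), CD300LB (2.09 ± 0.19), CD180 (2.01 ± 0.18), CISH (1.31 ± 0.12) and the metalloproteinase ADAM8 (1.15 ± 0.12) rose as well, with adjusted p of at most 0.0016. CXCL8 fell by 1.37, CCL20 fell by 1.69, CXCL3 fell by 0.92, CXCL5 fell by 1.04 and CCL2 fell by 0.68. The adhesion molecule ICAM1 fell by 0.59, NFKBIZ fell by 0.59, the toll-like receptor TLR2 fell by 0.63 and the lipid droplet gene HILPDA fell by 0.73. The adjusted p of these 9 genes was at most 0.0172. ALOX15 (1.48, adjusted p = 0.0598 with the block), SOCS1 (0.92, adjusted p = 0.230) and VSIG4 (-0.31, adjusted p = 0.384) did not pass.

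Of 33 textbook response genes 9 rose and 1 fell with the block (20 and 2 adjusted over the list alone), and 0 passed without it (4 rose and 1 fell adjusted over the list alone). The response list's median was 0.59 (camera adjusted p = 4.30e-16, adjusted p = 0.0078 with an estimated correlation, and adjusted p = 0.121 with the block and an estimated correlation). The NF-kB list had a median of -0.55 (camera adjusted p = 1.24e-14, adjusted p = 0.0078 with an estimated correlation, and adjusted p = 0.0511 with the block and an estimated correlation), and 9 of its 23 members fell with the block. The neuronal list's median was -0.21 (camera adjusted p = 0.0013, adjusted p = 0.618 with an estimated correlation). With the block NEFM fell by 0.40 (adjusted p = 0.0445), NEFH, SLC17A6 and SNAP25 fell too, and the transcription factor RUNX1 rose by 0.43 ± 0.09 (adjusted p = 0.0436). None of 40 nociceptor genes passed in either fit, TRPV1 (-0.27, adjusted p = 0.0795 with the block), SCN9A (-0.19) and TRPA1 (0.03) included. CALCA (-0.22), TAC1 (-0.16), IL31RA (-0.21), OSMR (0.05), IL4R (0.00) and STAT6 (0.13) did not pass either. With the block the 95% intervals of TRPV1 (-0.42 to -0.13), SCN9A (-0.34 to -0.03), CALCA (-0.36 to -0.07) and IL31RA (-0.39 to -0.04) lay below 0. Those of STAT6 (0.01 to 0.25), IL13RA1 (0.05 to 0.34) and SOCS1 (0.18 to 1.65), which did not pass either, lay above 0. In the itch list IL1RL1 rose by 2.20 ± 0.41 with the block (adjusted p = 0.0307).

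The chemokine list was lower too (median -0.23, camera adjusted p = 5.43e-04, adjusted p = 0.0405 with an estimated correlation, and adjusted p = 0.130 with the block and an estimated correlation). Another 14 lists were called without keeping the call with an estimated correlation (adjusted p of 0.146 to 0.656). The lower ones were those of nociceptor, neuropeptide, pan-neuronal, synaptic, interferon response, immediate early, cholesterol and mitochondrial genes, and the higher ones those of fibroblasts, mural cells, macrophages, MHC class II, extracellular matrix and cell cycle. Axon growth (adjusted p = 0.0085), hypoxia (2.04e-04), axon guidance (0.0486) and endothelial (0.0208) lists were called with the block only, with adjusted p of 0.378 to 0.418 with an estimated correlation.

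**Figure D3:**
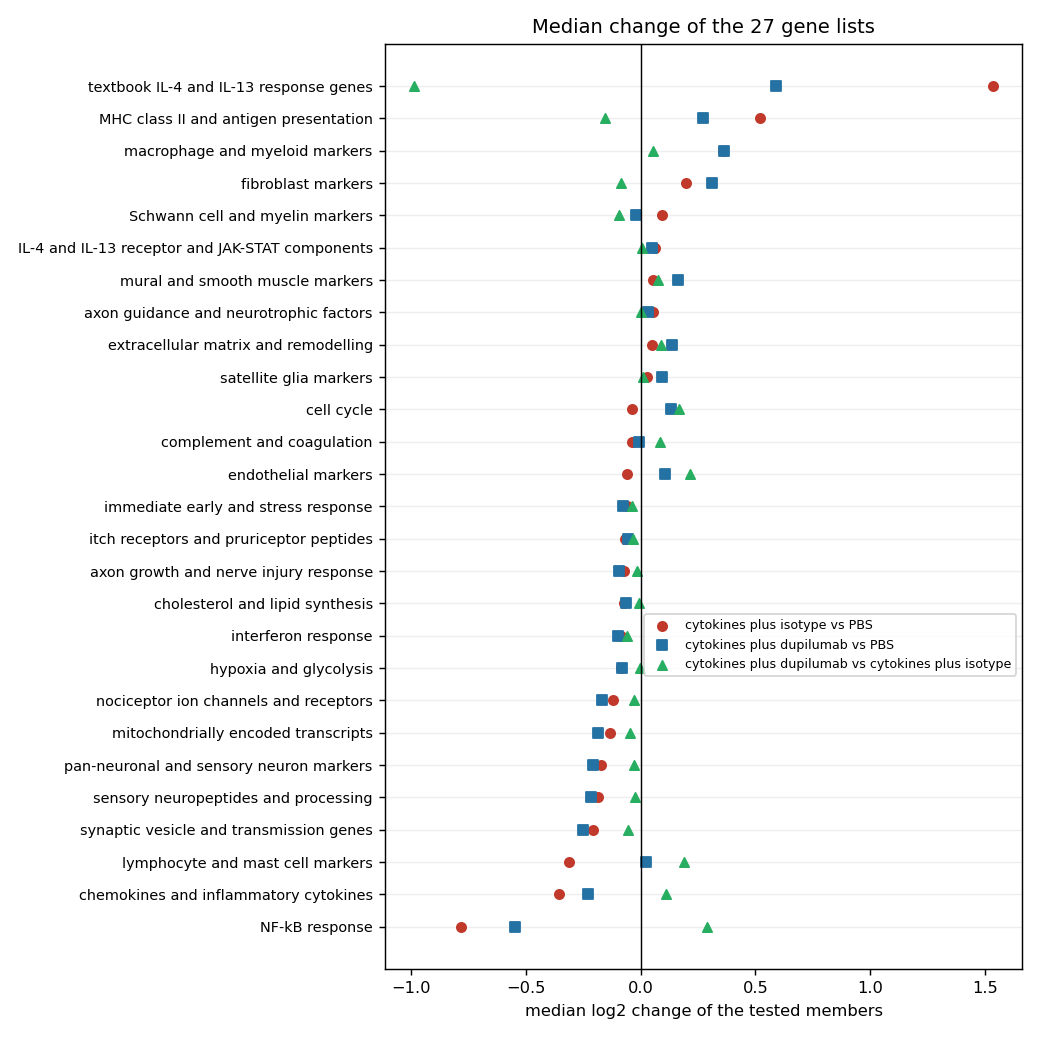
Median log2 change (horizontal axis) of the tested members of the 27 gene lists, with a marker per comparison. The textbook response list lies at 1.54 with cytokines plus isotype and 0.59 with cytokines plus dupilumab against PBS, while the pan-neuronal list lies at -0.17 and -0.21; medians close to 0 can change sign with the scaling of the libraries.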

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

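The fits with voom, and the fits with donor as a block without single libraries, were chosen after the data had been seen. The tests for whole counts that had been considered were not run, because whole counts were recovered for only part of the values. Depth limited the values near the floor of 3 counts. Fits without a donor leave 2 libraries per group, and those without 1 library assume that its group varies like the others. The causes of the changes below were not tested, except that fewer libraries enter the fits that leave some out.

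With donor as a block (replicate block) the counts of changed genes were 711, 100 and 193 in cytokines plus isotype against PBS, dupilumab against isotype and dupilumab against PBS, against 27, 0 and 0 without it. With donor as a random effect they were 407, 68 and 28, of which 401, 63 and 28 were also past the threshold with the block. With voom and the block they were 731, 122 and 193. For cytokines plus isotype against PBS without the block, the count was 17 with only the groups compared, 48 with array weights and 16 with voom, and 23 to 31 under the other pseudocounts, filters and scalings and without the trend. For dupilumab against isotype it was 8 with a pseudocount of 5 and 5 with array weights, and for dupilumab against PBS it stayed at 0 in these fits.

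Leaving out donors or libraries, the count for cytokines plus isotype against PBS without the block ranged from 0 to 24: 1 without replicate 2, 0 without replicate 3, 10 without PBS replicate 2, 14 without PBS replicate 3, 14 without PBS replicate 4, 10 without isotype replicate 2, 12 without isotype replicate 3, 16 without isotype replicate 4. With the block it ranged from 299 to 811: 308 without replicate 2, 334 without replicate 3, 310 without isotype replicate 2, 299 without isotype replicate 3. For dupilumab against isotype it stayed at 0 without the block and ranged from 36 to 175 with it: 55 without replicate 2, 36 without replicate 3, 175 without PBS replicate 4, 46 without isotype replicate 2, 38 without isotype replicate 3, 50 without dupilumab replicate 2, 51 without dupilumab replicate 3, 61 without dupilumab replicate 4. For dupilumab against PBS it ranged from 0 to 1 without the block (1 without PBS replicate 2, 1 without PBS replicate 3) and from 24 to 390 with it: 24 without replicate 2, 69 without replicate 4, 53 without PBS replicate 2, 390 without PBS replicate 3, 125 without PBS replicate 4, 67 without isotype replicate 3, 40 without dupilumab replicate 2, 47 without dupilumab replicate 4.

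The reversal by dupilumab, as the share of the cytokine change remaining, 45.1% without the block, was 57.3% with donor as a block, 51.4% with donor as a random effect and 57.7% with voom and the block. It was 39.9% with a pseudocount of 5, 49.0% with no filter and with the stricter filter, 50.7% with only the groups compared, 41.9% without the trend and 49.2% with voom, and 42.3% to 54.7% without single donors or libraries. For the reversal by dupilumab with donor as a block the latter range was 47.9% to 65.0%. Without the block it was not computed without replicate 2 or 3, for too few genes.

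The numbers of lists called, 9, 6 and 17, were 3, 2 and 3 with an estimated correlation, 3, 1 and 3 with fry, and 14, 10 and 21 with the replicate block. The lowest correlation between libraries of a donor, 0.59, was 0.46 with no filter, 0.74 with the stricter filter and 0.73 with a pseudocount of 5.

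For 227 changes of named genes without the block, 5000 of 5665 values kept their direction and side of the threshold, 104 lost the call, 427 gained it and 134 changed sign. With the block 3161 of 3859 kept both, 635 lost the call, 3 gained it and 60 changed sign. Of the sign changes, 134 and 60 were in genes past the threshold in neither of the fits compared. For the 81 list results 285 of 405 values kept both, 97 lost the call, 15 gained it and 8 changed sign.

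Sign changes in cytokines plus isotype against PBS gave IL13RA1 -0.014 with array weights. Without single donors or libraries the ranges (log2) were ADCYAP1 -0.88 to 0.14, ATF3 -0.26 to 0.40, CALCA -0.42 to 0.077, GAP43 -0.25 to 0.41, GBP2 -0.88 to 0.055. Others were IL13RA1 -0.081 to 0.10, IL13RA2 -0.069 to 0.27, IL2RG -0.16 to 0.82, IL31RA -0.43 to 0.15, IL4R -0.31 to 0.027. Others were KCNQ3 -0.85 to 0.049, NEFH -0.91 to 0.14, NEFL -0.69 to 0.051, OSMR -0.26 to 0.13, SCN9A -0.53 to 0.022. Others were SLC17A6 -0.66 to 0.079, SNAP25 -0.71 to 0.10, SYN2 -0.74 to 0.042, TAC1 -0.70 to 0.14, TRPA1 -0.56 to 0.41. Others were VEGFA -1.22 to 0.054. With the replicate block they were ATF3 -0.067 to 0.16, GAP43 -0.064 to 0.13, IL13RA1 -0.036 to 0.081, IL13RA2 -0.069 to 0.27, OSMR -0.11 to 0.018. Others were TRPA1 -0.36 to 0.36. Lists that changed direction without a call had adjusted p = 0.922 (itch receptors and pruriceptor peptides, fry), 0.727 (complement and coagulation, replicate block), 0.816 (complement and coagulation, replicate block with estimated inter-gene correlation).

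Sign changes in dupilumab against isotype gave GAP43 -0.027 with array weights, NPPB -0.019 with voom and the replicate block, SCN9A -0.0084 with array weights, STAT6 -0.0014 with quantile normalization. Without single donors or libraries the ranges (log2) were ATF3 -0.43 to 0.30, CALCA -0.29 to 0.17, GAP43 -0.35 to 0.37, IL2RG -0.54 to 0.35, IL31RA -0.41 to 0.22. Others were IL4R -0.081 to 0.25, JAK1 -0.0091 to 0.072, NPPB -0.34 to 1.027, OSMR -0.082 to 0.22, SCN9A -0.28 to 0.34. Others were STAT6 -0.065 to 0.083, TAC1 -0.38 to 0.54, TRPA1 -0.37 to 0.51, TRPV1 -0.21 to 0.13. With the replicate block they were ATF3 -0.16 to 0.044, CALCA -0.094 to 0.028, GAP43 -0.036 to 0.085, IL2RG -0.19 to 0.058, IL31RA -0.13 to 0.056. Others were JAK1 -0.0081 to 0.071, NPPB -0.046 to 0.59, SCN9A -0.010 to 0.077, STAT6 -0.0039 to 0.018, TAC1 -0.014 to 0.17. Others were TRPA1 -0.21 to 0.27, TRPV1 -0.075 to 0.010. Lists that changed direction without a call had adjusted p = 0.935 (axon growth and nerve injury response, replicate block with fry), 0.992 (hypoxia and glycolysis, fry), 0.682 (hypoxia and glycolysis, replicate block), 0.933 (hypoxia and glycolysis, replicate block with estimated inter-gene correlation), 0.950 (hypoxia and glycolysis, replicate block with fry).

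Sign changes in dupilumab against PBS gave ATF3 0.065 with array weights, IL4R -0.0032 with median-ratio scaling, IL4R -0.023 with array weights, IL4R -0.015 with voom, IL4R -0.010 with voom and the replicate block, TRPA1 -0.027 with voom, TRPA1 -0.041 with voom and the replicate block. Without single donors or libraries the ranges (log2) were ATF3 -0.38 to 0.35, GAP43 -0.23 to 0.41, IL2RG -0.29 to 0.75, IL31RA -0.56 to 0.080, IL4R -0.20 to 0.15. Others were NEFH -0.92 to 0.058, NPPB -1.05 to 0.21, OSMR -0.18 to 0.20, RUNX1 -0.094 to 0.85, SCN9A -0.51 to 0.062. Others were SLC17A6 -0.69 to 0.026, TAC1 -0.62 to 0.23, TLR2 -1.46 to 0.24, TNFRSF12A -0.11 to 0.92, TRPA1 -0.51 to 0.45. Others were VEGFA -1.04 to 0.13. With the replicate block they were ATF3 -0.16 to 0.13, GAP43 -0.030 to 0.13, IL2RG -0.031 to 0.32, IL4R -0.071 to 0.11, OSMR -0.038 to 0.098. Others were TRPA1 -0.26 to 0.34.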

Other observations

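The tests of myeloid cells, of library scaling, neuronal RNA share and the antibody, of the textbook response list and of lysosomal genes were chosen after the results were seen. Those in left-out donors and over other splits of the libraries were chosen before.

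Some lysosomal genes were higher with the cytokines. Of 48 tested genes of lysosomal enzymes and membrane proteins, a list drawn up after values had been seen, 16 rose and 0 fell in cytokines plus isotype against PBS with donor as a block, and 0 passed without it (limma). The proteases CTSC (3.02 ± 0.15, adjusted p = 4.83e-07), CTSL (1.01 ± 0.10) and CTSZ (0.97 ± 0.08), the lipase LIPA (1.01 ± 0.09) and the phosphatase ACP5 (1.63 ± 0.17) were among them. Against isotype, CTSC, LIPA and CTSZ fell with dupilumab with the block. A hypothesis is that the cytokines raise lysosomal genes as a group. The list's median was 0.23, and camera with an estimated correlation and the block gave p = 0.0108, on genes partly known beforehand, of which 32 did not pass.

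Many of the leading genes are known from myeloid cells, and a larger share of such cells in the cytokine cultures could raise them. That would raise macrophage markers together. Of 25 markers fixed beforehand, all of them expressed in these cultures, 8 rose with donor as a block while 4 (MARCO, VSIG4, CD14 and LYZ, the last named after its values were seen) fell by more than 1 (log2), which argues against a larger share as the whole cause. Abundant markers moved apart too, CD14 from 8.84 ± 0.53 to 6.84 ± 0.46 and CD74 from 10.23 ± 0.22 to 10.83 ± 0.28. A response of the cells to the cytokines, which the design names, stays open, with or without a change in share.

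The medians of the neuronal list were slightly below 0 in both cytokine groups against PBS, and its calls were lost with an estimated correlation (adjusted p = 0.743 and 0.618). With donor as a block the former was 0.300. A scaling factor shifts all genes of a library alike, and the median of all genes with cytokines plus isotype was -0.0107. That argues against library scaling for the list's lower place among the genes. For the list's distance from 0 scaling stays open. The higher of the list's medians under median-ratio scaling and quantile normalization was -0.17. However, these scalings moved the median of all genes too little (from -0.0107 to -0.0174 and -0.0217) to test it. A smaller share of neuronal RNA stays open too, since the 81.6% of the 38 markers below 0 in both comparisons, which share the PBS libraries, only restate the pattern. The antibody present in both cytokine groups cannot be told apart from the cytokines, since no group had an antibody alone; the list's median between the antibody groups was -0.0286. A response of the neurons to the cytokines stays open.

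Part of the change against PBS remained with dupilumab. Choosing genes on the libraries that measure them could exaggerate the reversal or leave a false remainder. Genes selected with donor as a block in 2 donors were therefore measured in the donor left out, where 48.4%, 36.7% and 75.6% of the median change remained without replicates 2, 3 and 4 in the selection. Selected without the block, 1 and 22 genes gave 47.9% and 42.4% without replicates 2 and 4, and 0 genes were selected without replicate 3. The lowest with the block, 36.7%, argues against a remainder made by selection. The highest with the block, 75.6%, missed the bound set beforehand for excluding selection as a source of the reversal, so that stays open for the size of the reversal over the selected genes. The textbook response list, fixed before the data were examined, was lower with dupilumab than with isotype without and with donor as a block (the larger adjusted p with an estimated correlation was 0.0265), which argues against selection for this list. An incomplete block of the receptor was not tested and stays open. An effect of the antibodies, absent from PBS, cannot be told apart from this remainder.

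All 10 splits of the 6 libraries of each comparison into 3 and 3 were also fitted, too few for a share under 0.05. The other splits mix both groups under each label, so real changes enter their spread and lower their counts. Their counts therefore do not show what unchanged groups would give. For cytokines plus isotype against PBS the real split gave 27 genes without the block and 711 with it, and the highest other split 0 in both, so that 1 of 10 splits gave as many. For dupilumab against isotype all 10 splits gave 0 genes without the block, and with it the real split gave 100 and the highest other 1. For dupilumab against PBS all 10 splits gave 0 without the block, and with it the real split gave 193 and the highest other 0. Among the 4 splits that part all 3 donor pairs, as the real one does, the highest other counts with the block were 0, 1 and 0.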
